A study of Arabidopsis thaliana with 7 samples.

How the data were processed

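The series holds ribosome footprints, poly(A) RNA, double-stranded RNA and small RNA from roots of seedlings grown with 500 µM or 0 µM phosphate; small RNA from low phosphate roots was not analysed here. The labels give the tagged line as RPL18B in the protocols and by another name in the sample characteristics. The treatment text of the low phosphate poly(A) and dsRNA samples repeats the control text, so their condition was taken from the sample titles. The series' design text states 2 bioreplicates, which the tables hold as numbered columns.

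Reads were handled by the authors with CASAVA 1.8, TopHat 1.3.1 and Bowtie2 2.2.9 against TAIR10, per the submitters' processing notes, which do not give each tool's role. The read counter and its strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes may share reads. The deposited counts are raw whole reads per gene for the coding and dsRNA tables and per transcript for the noncoding table. The deposited UTR values are RPKM, reads scaled to region length and library total, as the authors' table is titled. The deposited uORF values are whole numbers that are a score and not reads: within a uORF they are truncated multiples of 1 step, whose origin is not given in the sources used here. The deposited small RNA table gives counts per locus, a strand fraction and a phasing score per the file headers, and the libraries behind its totals are not given in the sources used here. The fraction and phasing score were not used in a test.

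Gene names came from a reference table of assembly TAIR10.1, used for names and neighbours only; 26719 of 27416 coding identifiers matched, and 358 of 2381 noncoding features had a locus there. Coordinates of noncoding RNAs are those of the deposited table. No per-sample column was left unused.

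Coding counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, the default expression filter by group, a quasi-likelihood fit of the 8 libraries of 4 groups and two-sided tests of low phosphate against control in poly(A) RNA, in footprints, and of their difference (translational efficiency). The dsRNA counts were fitted on their own 4 libraries. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05, and errors of log2 changes are SE. Gene lists (16 lists, 301 members, 1 dropped because its symbol differed from the reference) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. In the tests, noncoding counts used coding library sizes for footprints and their own totals for poly(A) RNA, since the poly(A) columns did not follow the same-named coding columns. The design had coding sizes for all columns. The ratio of footprints to poly(A) RNA in control roots was computed with those coding sizes. The design had edgeR for uORFs; because the values are scores, limma on log2(score + 10) was used, for uORFs with a mean score of at least 100 and 1 uORF per gene. The uORF to coding ratio used a prior count of 0.5 and at least 10 footprints. UTRs were tested with limma on log2(RPKM + 0.5) for regions with a mean RPKM of at least 1. These changes understate the fold of low regions. The recovered reads, 100% of them whole within 0.01, were tested with edgeR as an alternative.

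Genes were named by a rule fixed before the data were examined, as were the lists and most alternatives. The rule took the 10 largest called changes each way with a mean log2 CPM of at least 1 and both low phosphate libraries beyond both control libraries, at most 2 of them unnamed. It added up to 4 genes of smallest p from each list with a called member, and SPX1, PHT1;1, PHO1, PHO2, IPS1 and the tagged protein's gene always. Folds against a group with 0 counts are bounds from 3 counts over the group; such floors, and counting intervals, cover counting error only.

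The depth was 7156329 to 12817826 footprints, 18262547 to 26746252 poly(A) reads and 2735264 to 8249514 dsRNA reads per library, so that 3 counts equal 0.112 CPM in the deepest poly(A) library and 0.419 CPM in the shallowest footprint library. Simulated data with known changes were run through the tests of coding poly(A) RNA, footprints and efficiency, dsRNA, noncoding poly(A) RNA and footprints, uORF and UTR footprints, the uORF to coding ratio, and 1 gene list by camera. The other efficiency tests, the poly(A) tests of uORFs and UTRs and the test of dsRNA against poly(A) RNA were not simulated. Of 4-fold changes, 93.9% were recovered in coding poly(A) RNA, 85.7% in footprints, 95.2% in dsRNA and 18.3% for footprints of noncoding RNAs. With pairs, 91.3% of 4-fold and 51.6% of 2-fold efficiency changes were recovered, in data simulated with pairs. Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, the replicate number as a block, footprint and poly(A) libraries as pairs, separate fits, other pseudocounts and minimums, and leaving out each library in turn. The figures were drawn with matplotlib 3.10.9.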

Results

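Roots of Arabidopsis thaliana seedlings aged 14 d were compared after 7 d on medium with 500 µM phosphate (control) or 0 µM phosphate (low phosphate). The plants carried a FLAG-tagged ribosomal protein, through which ribosomes were captured, and the RNA fragments of 26 to 32 nt that they protected were sequenced as ribosome footprints. Poly(A) RNA and double-stranded RNA (dsRNA) of roots were sequenced as well, and each of these 3 assays had 2 bioreplicates per condition. The dsRNA libraries came from another extract, line label and kit than the others. Small RNA was analysed for control roots. Footprint counts over coding sequences summed to 7156329 and 7324092 in the control libraries and to 12817826 and 8940746 in the low phosphate libraries. Poly(A) counts summed to 26746252 and 18262547 in control and to 21415342 and 26722907 in low phosphate. The dsRNA libraries were shallower, with 8249514 and 3246810 counts in control and 4683670 and 2735264 in low phosphate. The comparisons ask which transcripts change in amount and in ribosome occupancy when roots lack phosphate.

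In poly(A) RNA, genes for phosphate release, membrane lipid replacement and phosphate transport rose in low phosphate roots. The phosphatase gene PS2 rose 32.3-fold, a log2 change of 5.01 ± 0.16 (SE, n = 2 per condition, edgeR adjusted p = 1.08e-06). MGDC, a galactolipid synthase gene, rose by 5.44 ± 0.31 on the log2 scale (edgeR adjusted p = 5.04e-05), and PEPC1, another phosphatase gene, by 6.44 ± 0.58 (edgeR adjusted p = 0.000948). The noncoding RNA IPS1, which sequesters a microRNA of phosphate signalling, rose by 6.30 ± 0.65 (edgeR adjusted p = 0.00268), and its relative AT5G03545 by 5.14 ± 0.48 (edgeR adjusted p = 0.00159). Among the genes that fell were GSTF14, which fell by 2.55 ± 0.22 (edgeR adjusted p = 0.00066), and SKOR, a potassium channel gene of the stele, which fell by 1.68 ± 0.14 (edgeR adjusted p = 0.000605). In all, 185 genes rose and 50 fell of 19866 tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Without control replicate 1 the test called 52 higher and 7 lower, and without control replicate 2 it called 97 and 22. Without low phosphate replicate 1 it called 94 and 7, and without low phosphate replicate 2 it called 97 and 20.

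Of the 24 tested genes of phosphate uptake and signalling, 10 rose in poly(A) RNA, 1 fell and 13 were not called, against 12 higher and 2 lower when adjusted over the list alone. SPX3, a repressor of phosphate signalling, rose by 4.85 ± 0.34 (edgeR adjusted p = 0.000146). The transporter genes PHT1;2, PHT1;8 and PHT1;4 rose by 3.95 ± 0.25, 3.25 ± 0.21 and 2.43 ± 0.17. PHO2, whose product limits phosphate uptake, fell by 0.92 ± 0.15 (edgeR adjusted p = 0.0182), and this call ended without control replicate 1 (0.164), control replicate 2 (0.0748), low phosphate replicate 1 (0.105) or low phosphate replicate 2 (0.173). SPX1 had a log2 change of 1.96 ± 0.78 and was not called (edgeR adjusted p = 0.474); its control libraries held 35.6 and 219.7 CPM. PHT1;1, at 0.63 ± 0.17 (edgeR adjusted p = 0.159), and PHO1, at -0.11 ± 0.21 (edgeR adjusted p = 0.968), were not called either. Of 23 genes for phosphatases, nucleases and phospholipid replacement, 12 rose and 11 were not called, against 18 higher when adjusted over the list alone. They included the phospholipase genes NPC4, at 3.24 ± 0.17, and PLDP2, at 2.77 ± 0.20. Of 20 root hair cell markers, 10 rose and 10 were not called, against 13 higher when adjusted over the list alone, with RHS19, a peroxidase gene of root hairs, at 1.86 ± 0.18. The higher counts of phosphate uptake, phosphatase and root hair genes became 6, 9 and 2 without poly(A) control replicate 1, 7, 11 and 7 without control replicate 2, 7, 10 and 6 without low phosphate replicate 1, and 6, 10 and 5 without low phosphate replicate 2. All 3 lists stood above other genes by camera, with adjusted p of 3.79e-10, 5.78e-31 and 1.56e-22, and adjusted p = 0.0444, 0.00303 and 0.00303 with an estimated correlation.

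Genes of iron and nitrogen nutrition and of flavonoid synthesis were lower in poly(A) RNA. Of 25 iron homeostasis genes, 3 fell and 22 were not called, against 2 higher and 18 lower when adjusted over the list alone (camera adjusted p = 1.81e-12, and adjusted p = 0.0159 with an estimated correlation). NAS1, a nicotianamine synthase gene, fell by 2.04 ± 0.29 (edgeR adjusted p = 0.00906), and its call ended without control replicate 1 (0.0640) or low phosphate replicate 1 (0.0658). FRO2, a ferric chelate reductase gene, fell by 1.44 ± 0.22 (edgeR adjusted p = 0.014), and its call ended without control replicate 1 (0.0604), control replicate 2 (0.0926) or low phosphate replicate 1 (0.125). The iron transporter gene IRT1 was at -1.56 ± 0.32 and was not called (edgeR adjusted p = 0.0614). Of 15 nitrogen uptake and assimilation genes, 3 fell and 12 were not called, against 7 lower when adjusted over the list alone (camera adjusted p = 5.04e-09, and adjusted p = 0.0444 with an estimated correlation). The nitrate transporter gene NRT1.1 fell by 1.44 ± 0.15 (edgeR adjusted p = 0.00159). Of 5 measured flavonoid and anthocyanin synthesis genes, 2 fell and 3 were not called, with 2 lower when adjusted over the list alone (camera adjusted p = 4.2e-06, and adjusted p = 0.0305 with an estimated correlation). FLS1, a flavonol synthase gene, fell by 1.36 ± 0.17 (edgeR adjusted p = 0.00518), and its call ended without control replicate 1 (0.0606) or low phosphate replicate 2 (0.0516). The edgeR counts of lower iron, nitrogen and flavonoid genes became 0, 1 and 0 without poly(A) control replicate 1, 2, 1 and 1 without control replicate 2, 0, 1 and 1 without low phosphate replicate 1, and 3, 1 and 0 without low phosphate replicate 2.

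Of 12 sulfate uptake and assimilation genes, 2 rose and 10 were not called in poly(A) RNA, against 2 higher and 3 lower when adjusted over the list alone. The sulfate transporter genes SULTR1;1 and SULTR1;3 rose by 2.03 ± 0.21 and 3.05 ± 0.40, while the list's median was -0.71, and the list was not called (camera adjusted p = 0.238). In the control libraries alone, the median poly(A) level of this list differed by -1.09 on the log2 scale between replicate 2 and replicate 1, and that of 23 photosynthesis genes, markers of green tissue, by 1.37. Lists called by camera differed too: phosphate uptake by 0.21, phosphatases by 0.15, flavonoid synthesis by 0.32 and ribosomal proteins by 0.19, each beyond at least 99.4% of 10000 random lists of like expression. Their medians between conditions were 0.74, 1.78, -1.04 and 0.15. Genes of the random lists were drawn singly, so the comparison with them does not allow for list members that vary together. Both tested members of the named noncoding RNA list, IPS1 and AT5G03545, rose. Of 13 genes with conserved peptide upstream reading frames 1 rose, 1 fell and 11 were not called, the same counts as when adjusted over the list alone (camera adjusted p = 0.68); without poly(A) control replicate 1 neither was called. SUS4, a sucrose synthase gene, was the 1 gene called of 11 in the low oxygen list and rose by 1.59 ± 0.20, with 1 higher when adjusted over the list alone (camera adjusted p = 0.656). No member was called by edgeR among 34 cytosolic ribosomal protein genes, 17 endodermis markers, 19 meristem and cell division markers, 13 jasmonate genes, 12 vascular markers and the 23 photosynthesis genes. When adjusted over the list alone the count of higher members was also 0 in each, with 1 vascular marker lower. The ribosomal protein list stood above other genes by camera (adjusted p = 0.00224), a call lost at adjusted p = 0.686 with an estimated correlation. The endodermis list did so too (camera adjusted p = 0.00356), a call lost at adjusted p = 0.244 with an estimated correlation. So did the meristem list (camera adjusted p = 0.00241), a call lost at adjusted p = 0.0612 with an estimated correlation. By fry the meristem list was called higher (adjusted p = 0.00901), and the ribosomal protein and endodermis lists were not called (0.575 and 0.147). Photosynthesis, jasmonate and vascular lists were not called, with camera adjusted p of 0.0535, 0.391 and 0.369.

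Footprints of phosphatase, lipid and phosphate transport genes also rose in low phosphate roots. PS2 footprints rose by 4.91 ± 0.16 on the log2 scale (n = 2 per condition, edgeR adjusted p = 1.85e-06), MGDC by 4.95 ± 0.33 (edgeR adjusted p = 0.000179) and PEPC1 by 6.36 ± 0.61 (edgeR adjusted p = 0.00135). Of 23 genes for phosphatases, nucleases and phospholipid replacement, 14 rose and 9 were not called, against 21 higher when adjusted over the list alone. Of 24 phosphate uptake and signalling genes, 9 rose and 15 were not called, against 12 higher and 2 lower when adjusted over the list alone, with PHT1;2 at 4.35 ± 0.30 and SPX3 at 4.23 ± 0.36. Of 20 root hair markers, 12 rose and 8 were not called, against 16 higher when adjusted over the list alone, with RHS19 at 2.07 ± 0.18 and LRX1, a cell wall protein gene, at 1.32 ± 0.13. The higher counts of phosphatase, phosphate uptake and root hair genes became 9, 7 and 7 without footprint control replicate 1, 10, 7 and 11 without control replicate 2, 11, 8 and 8 without low phosphate replicate 1, and 11, 8 and 9 without low phosphate replicate 2. These 3 lists kept their camera calls, with adjusted p = 0.00208, 0.0287 and 0.00208 with an estimated correlation. Of 25 iron genes 2 fell and 23 were not called, against 10 lower when adjusted over the list alone, and of 15 nitrogen genes 2 fell and 13 were not called, against 7 lower when adjusted over the list alone. NAS1 fell by 2.15 ± 0.29 (edgeR adjusted p = 0.00669), NRT1.1 fell by 1.48 ± 0.15 (edgeR adjusted p = 0.00171) and the copper transporter gene COPT2 fell by 1.81 ± 0.20 (edgeR adjusted p = 0.00221). Adjusted p was 0.0232 for iron and 0.0364 for nitrogen with an estimated correlation. DESeq2 called 6 iron and 3 nitrogen genes lower, and edgeR with the replicate block called 10 and 4. Lower iron and nitrogen genes numbered 2 and 1 without footprint control replicate 1, 1 and 1 without control replicate 2, 1 and 1 without low phosphate replicate 1, and 2 and 3 without low phosphate replicate 2. Of 5 anthocyanin genes 2 fell and 3 were not called, against 3 lower when adjusted over the list alone (camera adjusted p = 7.61e-07, and adjusted p = 0.024 with an estimated correlation), and 1 was called without footprint control replicate 2 or either low phosphate replicate. SULTR1;1 and SULTR1;3 were the 2 sulfate genes of 12 that rose, by 2.43 ± 0.23 and 4.26 ± 0.50, with 10 not called. With the replicate block, 2 sulfate genes were called higher and 2 lower. The 17 endodermis markers held no called gene and stood above other genes by camera (adjusted p = 0.0394), a call lost at adjusted p = 0.461 with an estimated correlation. Between control replicates 2 and 1 the median footprint level differed by -1.18 for the sulfate list, 0.99 for photosynthesis, 0.38 for ribosomal proteins and 0.18 for phosphate uptake.

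The quasi-likelihood test of edgeR called 181 genes with more and 56 with fewer footprints of 19866. Without control footprint replicate 1 the counts were 74 and 19, and without low phosphate footprint replicate 1 they were 105 and 16. Of the genes called in poly(A) RNA, 132 rose and 39 fell in footprints too, and 0 went the opposite way. The 19866 log2 changes of both assays correlated across genes at a Pearson coefficient of 0.512; genes are not independent replicates. Deviations of same-numbered libraries of both assays correlated at 0.37 in control and 0.54 in low phosphate, so shared replicate differences add to this overlap and coefficient, by an amount that was not tested. The methyltransferase gene XPL1, from the list of genes with conserved peptide upstream reading frames, rose by 2.99 ± 0.30 in footprints (edgeR adjusted p = 0.00156) and by 1.61 ± 0.26 in poly(A) RNA (edgeR adjusted p = 0.0161). The poly(A) call of XPL1 ended without control replicate 1 (0.187), control replicate 2 (0.123) or low phosphate replicate 1 (0.108). SPX1 had 60.5 and 278 CPM of footprints in the control libraries and was not called at 1.91 ± 0.78 (edgeR adjusted p = 0.388).

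Translational efficiency, the ratio of footprints to poly(A) RNA, changed past the threshold for no gene when libraries were not paired: edgeR's interaction test called 0 of 19866 genes, with 397 at an unadjusted p under 0.05, and DESeq2 called 0, with 276 at an unadjusted p under 0.05. With same-numbered footprint and poly(A) libraries of a condition as pairs, a fit chosen after the data were seen, edgeR called 3 genes higher and 5 lower, with 1559 at an unadjusted p under 0.05. With these pairs limma voom called 4 and 5, and DESeq2 called 0, with 515 at an unadjusted p under 0.05. XPL1 was called higher with pairs, at 1.35 ± 0.23 (edgeR adjusted p = 0.00324, limma voom 0.0490, DESeq2 0.206). The others called higher by edgeR were UGP3 and AT2G14910. Those lower were MT1A, AT5G59690 and the plastid genes ATCG00330, ATCG00140 and ATCG00470, and all of these were named after their values were seen. For plastid genes the ratio is not read as translation, since capture of plastid ribosomes through the tagged protein was not tested. Limma voom did not call UGP3 (adjusted p = 0.193) or ATCG00140 (adjusted p = 0.319), and DESeq2 called none of the 8, with adjusted p from 0.206 to 1.00. MT1A, a metallothionein gene, fell by 1.08 ± 0.17 with pairs (edgeR adjusted p = 0.00279, limma voom 0.000239, DESeq2 1.00). Without pairs XPL1 had the log2 change 1.38 ± 0.39 (edgeR unadjusted p = 0.00539, adjusted p = 1.00). SPX1 was at -0.05 ± 1.07, PHO2 at 0.41 ± 0.21 and PHT1;1 at -0.02 ± 0.23, none of them called with or without pairs. Without pairs no list had a called member, and the iron and conserved peptide lists, with medians of -0.07 and -0.24, and the nitrogen list, at 0.01, had camera directions opposite to their medians. Ribosomal protein genes were lower as a list by camera (adjusted p = 0.000541, median -0.17), a call lost at adjusted p = 0.899 with an estimated correlation. Photosynthesis genes were lower too (camera adjusted p = 0.026, median -0.41), a call lost at adjusted p = 0.899 with an estimated correlation. On simulated counts of this depth the test without pairs recovered 74.6% of 4-fold and 7.94% of 2-fold changes. The simulated libraries varied independently, whereas the real same-numbered footprint and poly(A) libraries deviated together, at correlations of 0.37 and 0.54. These recovered shares therefore need not hold for the real libraries. The 397 genes at an unadjusted p under 0.05 without pairs were fewer than that cutoff alone would give if nothing changed.

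**Figure D1:**
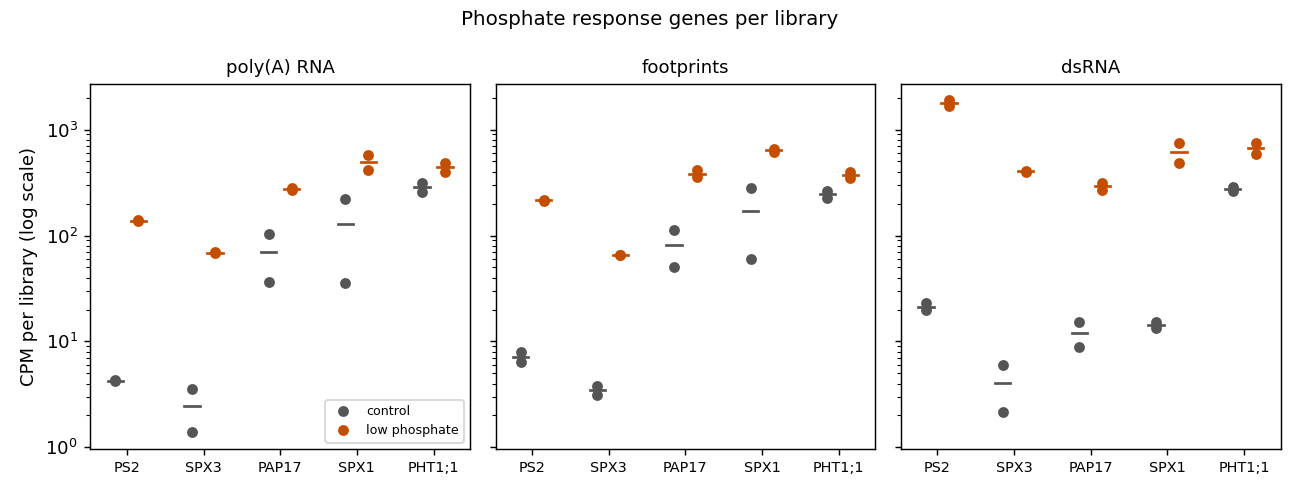
CPM (library-scaled counts, log axis) of 5 phosphate response genes in each library, with control in grey and low phosphate in orange; points are libraries and short lines their means (n = 2). In poly(A) RNA the control libraries of SPX1 lie at 35.6 and 219.7 CPM and those of low phosphate at 413 and 579.8 CPM.

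In dsRNA, the genes that rose included the same phosphate response genes. PEPC1 rose by 7.01 ± 0.32 on the log2 scale (n = 2 per condition, edgeR adjusted p = 4.08e-102), IPS1 by 7.47 ± 0.36 (edgeR adjusted p = 1.11e-90) and SPX3 by 6.62 ± 0.31 (edgeR adjusted p = 7.26e-95). SPX1 rose by 5.61 ± 0.29 (edgeR adjusted p = 5.4e-80), from 13.5 and 15.1 CPM in control to 484 and 741 CPM in low phosphate. The ribonuclease gene RNS1 had 0 counts in control and was at least 30.5-fold higher, against a floor of 3 counts over the group. GSTF14 fell by 4.83 ± 0.30 (edgeR adjusted p = 3.74e-54) and NAS1 fell by 3.45 ± 0.26 (edgeR adjusted p = 1.24e-38). Of 17570 genes tested, 1787 rose and 978 fell. Without control replicate 1 the counts were 624 and 195, without control replicate 2 they were 729 and 205, and without low phosphate replicate 2 they were 2925 and 2293. The fit took a spread shared between genes of like expression level, so no gene's own spread entered its test. The common biological coefficient of variation of these libraries was estimated at 0.145.

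Of 26 phosphate uptake and signalling genes, 17 rose, 1 fell and 8 were not called in dsRNA, against 17 higher and 2 lower when adjusted over the list alone. Of 23 phosphatase, nuclease and lipid genes 20 rose and 3 were not called, and of 19 root hair markers 17 rose and 2 were not called, with 20 and 17 higher when adjusted over the list alone. SRG3, a phosphodiesterase gene, rose by 5.36 ± 0.28, RHS19 by 2.90 ± 0.24 and PRP3 by 2.66 ± 0.24. For these 3 lists alone the camera calls held with an estimated correlation (adjusted p = 0.0304, 0.0287 and 0.037). Of 22 iron genes 2 rose, 11 fell and 9 were not called, against 2 higher and 13 lower when adjusted over the list alone, with IRT1 at -1.69 ± 0.23. Of 12 sulfate genes 2 rose, 8 fell and 2 were not called, with 2 and 8 when adjusted over the list alone; SULTR1;3 rose by 5.35 ± 0.40, and APR3, of sulfate reduction, fell by 2.25 ± 0.24. Of 15 nitrogen genes 2 rose, 7 fell and 6 were not called, against 2 higher and 8 lower when adjusted over the list alone, with NRT1.1 at -2.16 ± 0.24. The camera calls of iron, sulfate and nitrogen (adjusted p = 3.99e-07, 2.33e-05 and 0.000212) were each lost at adjusted p = 0.191 with an estimated correlation. Of 16 endodermis markers 9 rose and 7 were not called, against 10 higher when adjusted over the list alone. Their camera call (adjusted p = 0.00248) was lost at adjusted p = 0.191 with an estimated correlation. By fry, which does not compare a list with other genes, the iron, sulfate, nitrogen and endodermis lists were called (adjusted p = 0.0365, 0.0433, 0.0159 and 0.0159). Low oxygen and photosynthesis lists were not called by fry (adjusted p = 0.0566 and 0.0814). No endodermis marker was called by edgeR without control replicate 1 or without control replicate 2, where CYP86B1, CASP1, GPAT5 and ESB1, the members of smallest p, had adjusted p from 0.133 to 0.452 and from 0.164 to 0.474. Without these control libraries in turn, root hair calls became 12 and 12, lower iron calls 5 and 6, lower sulfate calls 4 and 4, and lower nitrogen calls 1 and 2, and no iron or nitrogen gene was called higher.

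Of 9 low oxygen genes in dsRNA, 3 rose, 1 fell and 5 were not called, against 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00152, lost at adjusted p = 0.301 with an estimated correlation). SUS4 rose by 2.78 ± 0.26 and the alcohol dehydrogenase gene ADH1 by 2.08 ± 0.34. With DESeq2 or with the replicate block, 3 low oxygen genes were called higher and 0 lower. Of 16 photosynthesis genes 1 rose, 3 fell and 12 were not called, against 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0169, lost at adjusted p = 0.335 with an estimated correlation). Each of these 4 calls depended on the setting: DESeq2 called 1 photosynthesis gene, without control replicate 1 only LHCA1 was called, and without control replicate 2 only PRK was. PRK and LHCA1 were not called without low phosphate replicate 1 (edgeR adjusted p = 0.161 and 0.101). Of 9 jasmonate genes 2 rose, 2 fell and 5 were not called, with 3 higher and 2 lower when adjusted over the list alone; VSP2, a wound and jasmonate response gene, fell by 3.24 ± 0.34. SUC2, a phloem sucrose transporter gene, was the 1 vascular marker of 11 that rose, by 1.91 ± 0.25. Jasmonate, vascular, meristem, ribosomal protein, anthocyanin and conserved peptide lists were not called by camera, with adjusted p of 0.688, 0.438, 0.688, 0.143, 0.438 and 0.76; the meristem list's median was 0.04 while its test pointed lower. Among genes called in poly(A) RNA and tested in both assays, 173 rose and 39 fell in dsRNA too, where independent lists would share 18.4 and 2.79, and 0 went the opposite way. Deviations of same-numbered poly(A) and dsRNA libraries correlated at -0.02 in control and 0.017 in low phosphate.

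**Figure D2:**
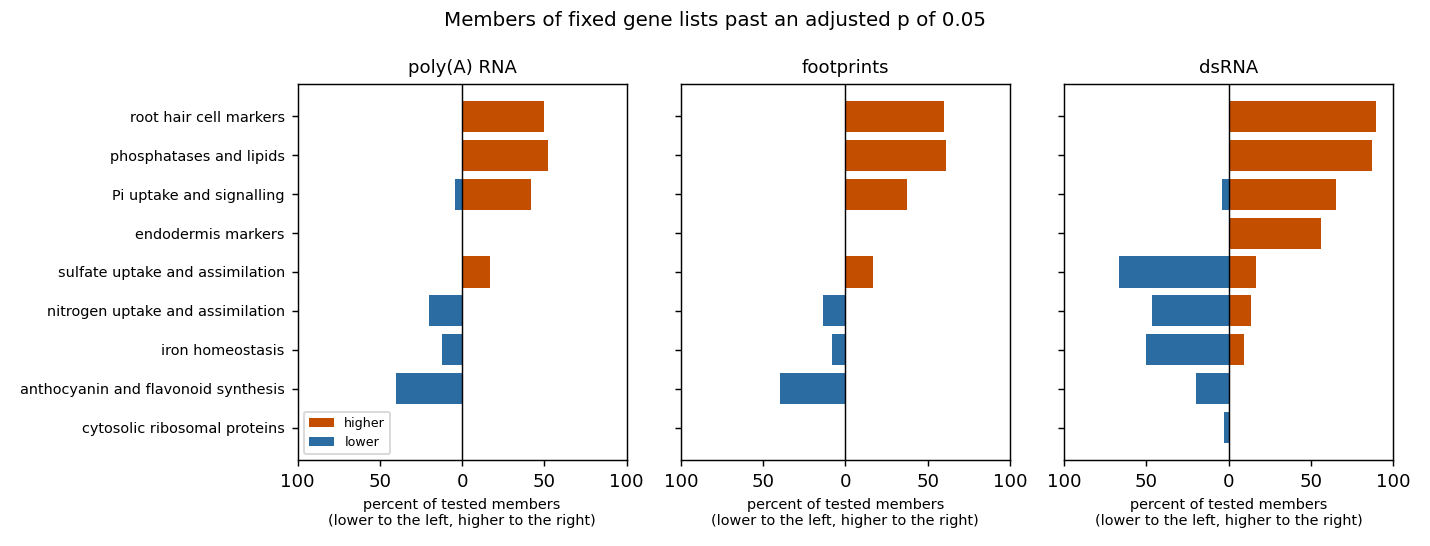
Percent of the tested members of 9 fixed gene lists that were called lower (blue, to the left of 0) or higher (orange, to the right) in low phosphate, for poly(A) RNA, footprints and dsRNA. Of the tested root hair markers, 17 of 19 were called higher in dsRNA and 10 of 20 in poly(A) RNA. Of all tested genes, 1787 of 17570 and 185 of 19866 were called higher, and the difference between assays was not tested for this list.

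In the noncoding table, IPS1 and its relative carried more footprints in low phosphate. IPS1 had 0 footprints in control and was at least 16.7-fold higher, against a floor of 3 counts over the group (edgeR adjusted p = 2.76e-07). AT5G03545 footprints rose by 4.33 ± 0.55 (n = 2 per condition, edgeR adjusted p = 2.64e-12). In the coding table IPS1 had 0 footprints in control and 19 in low phosphate and was not called (edgeR adjusted p = 0.505), and AT5G03545, with 0 in control, was not called either (edgeR adjusted p = 0.308). Footprints of TAS2 and TAS1C, precursors of trans-acting small interfering RNAs, fell by 1.70 ± 0.45 (edgeR adjusted p = 0.00996) and fell by 1.43 ± 0.43 (edgeR adjusted p = 0.0449). Of 2229 noncoding RNAs tested, 14 had more and 32 had fewer footprints. Of the 32, 19 lie on chromosome 3 between positions 13594180 and 13866977 of TAIR10. These 19 held 1520 and 995 footprints in control but 87 reads in all poly(A) libraries together. Their calls are not read as lost ribosome occupancy, since the origin of their fragments was not tested. Scaled to the noncoding table's own totals, 61.4% of the calls were higher, against 30.4% with coding library sizes. Without footprint libraries of control replicate 1, control replicate 2, low phosphate replicate 1 and low phosphate replicate 2 in turn, the higher counts were 9, 14, 8 and 9 and the lower counts 4, 55, 0 and 16, so the calls of TAS2 and TAS1C ended without low phosphate replicate 1.

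In the libraries labelled by condition in the noncoding table, poly(A) RNA of IPS1 fell by 6.45 ± 0.51 and that of AT5G03545 fell by 5.19 ± 0.53, opposite to the coding table. Under those labels edgeR called 1 noncoding RNA higher and 24 lower, and 12 of 12 called in both assays went opposite ways. Without poly(A) control replicate 1 or 2 the lower count was 11 or 9, and without low phosphate poly(A) replicate 1 or 2 it was 9 or 11; the count of 1 higher became 0 or 2 with any single library left out. No direction for the poly(A) RNA of noncoding transcripts is therefore drawn from this table. The ratio of footprints to poly(A) RNA gave 22 higher and 5 lower calls as labelled, and 0 of either with the labels exchanged, with 155 at an unadjusted p under 0.05 by edgeR. Its lower count was 34, 1 and 13 without footprint libraries of control replicate 2, low phosphate replicate 1 and low phosphate replicate 2. It was 1 without either poly(A) control replicate and 0 without low phosphate poly(A) replicate 1. In control roots, with coding library sizes for all columns, the median log2 ratio of footprints to poly(A) RNA was -2.73 over 2089 noncoding RNAs and -0.02 over 20297 coding genes. Of the noncoding RNAs, 28.6% lay above the 10th percentile of coding genes, and 30.3% with the labels exchanged. The share was 53.5% over 331 annotated noncoding RNAs, with a median of -1.05, and 23.9% over 1758 new transcripts, with a median of -3.05; this difference was not tested. The medians depended on the prior count: with a prior count of 2 they were -1.68 over all, -0.87 for annotated and -1.77 for new transcripts.

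Upstream open reading frames (uORFs) were tested with limma on the deposited scores of 2220 genes. No uORF was called in footprints: limma called 0, with 83 at an unadjusted p under 0.05, and 1 higher with a pseudocount of 50 or without poly(A) control replicate 1 or 2. In poly(A) RNA 3 rose, among them that of IPS1 at 6.64 ± 0.82 (limma adjusted p = 0.0392), and 5 fell; without any 1 of the 4 footprint libraries or of the 2 low phosphate poly(A) libraries 0 were called in either direction. Without poly(A) control replicate 1 there were 12 higher and 86 lower, and without poly(A) control replicate 2 there were 10 and 11. The ratio of uORF to coding footprints gave 0 limma calls among 2198 genes, with 84 at an unadjusted p under 0.05, 14 higher and 70 lower. Its median was -0.36 and ran from -0.60 without control replicate 2 to -0.13 without low phosphate replicate 1. This shift was not tested. The median of uORF footprints themselves was -0.33, and 0.036 when libraries were scaled by their median ratio over uORFs. That scaling sets the median near 0 by construction, so the second value says nothing about the shift of the ratio. Without footprint control replicate 1 it gave 11 higher, without control replicate 2 it gave 54 higher and 36 lower, and without low phosphate replicate 2 it gave 6 lower. On simulated scores the footprint test recovered 21.7% of 4-fold and 46.8% of 8-fold changes.

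Footprints of 3' UTRs rose with those of their genes for a few phosphate response genes. No 5' UTR of a listed phosphate gene was called in footprints. The lowest limma adjusted p were 0.0782 for PS2, at a log2 change of 4.24 ± 0.51, and 0.084 for PEPC1, at 6.71 ± 0.88. In 3' UTRs, footprint RPKM of SPX3 rose by 3.92 ± 0.65 on the log2(RPKM + 0.5) scale (limma adjusted p = 0.00198). The 3' UTR of PS2 was listed at 0 in control footprints and at a mean of 39.1 ± 3.25 RPKM (SD, n = 2) in low phosphate (limma adjusted p = 2.82e-05). Poly(A) RPKM of 3' UTRs gave 18 higher and 5 lower calls of 21851 regions, and footprints 50 and 13. Some footprint calls, such as WRKY42 and AT5G09270, and most efficiency calls lay on regions shorter than a footprint. Several of the higher footprint regions belonged to AT3G17998, and 1 of them, at 6157233 to 6157551, overlapped the called 3' UTR of XPL1. Overlapping regions may share reads, so these counts are not counts of separate genes. The footprint counts became 176 and 97 without control footprint replicate 1, 933 and 551 without replicate 2, and 112 and 147 without low phosphate footprint replicate 2. Without low phosphate footprint replicate 1, 61 were lower. They became 16 and 3 without either poly(A) control replicate, and 25 and 3 or 28 and 3 without low phosphate poly(A) replicate 1 or 2. The poly(A) counts became 49 and 16 or 52 and 17 without control footprint replicate 1 or 2, and 33 and 11 or 34 and 12 without low phosphate footprint replicate 1 or 2. Without poly(A) control replicate 1 they were 11 and 1, without control replicate 2 there were 7 higher, without low phosphate replicate 1 there were 11 higher, and without low phosphate replicate 2 they were 1 and 2. In 5' UTRs, 7 regions were higher and 14 lower in poly(A) RNA, and 3 were higher in footprints, of 24033. The 3 footprint calls, SEC15A, AT4G01790 and NFXL2, all lay on regions shorter than a footprint, as did most of the poly(A) calls. These 5' UTR calls are therefore not read as changes of whole UTRs. Poly(A) calls were 68 and 56 without low phosphate poly(A) replicate 1, 12 and 11 without replicate 2, and 0 without any other library. Footprint calls were 226 and 53 without control footprint replicate 2, 0 without any other footprint library, 2 and 1 without either poly(A) control replicate, and 1 higher without either low phosphate poly(A) replicate. With the poly(A) denominators exchanged between conditions, as the coding totals would have them (CV 0.370% against 34.8% as named), limma called 0 of the 3' UTRs in poly(A) RNA, with 535 at an unadjusted p under 0.05, and 24 and 5 in footprints. In 5' UTRs it then called 13 and 25 in poly(A) RNA. Whole reads recovered from the RPKM gave edgeR counts of 54 and 10 for poly(A) RNA and 22 and 14 for footprints in 3' UTRs. Limma recovered 0% of simulated 16-fold changes in 5' UTRs and 25.4% in 3' UTRs, so footprint changes of that size were not detectable in most regions. Footprint density per poly(A) read in 5' UTRs was a median 4.05-fold and 2.78-fold that of the coding sequence in the control libraries and 2.14-fold and 3.14-fold in the low phosphate libraries. In 3' UTRs it was 0.236-fold and 0.194-fold in control and 0.141-fold and 0.178-fold in low phosphate. The difference between conditions was not tested.

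The small RNA table, which the control sample's description names and whose libraries are not stated, listed 25025 loci with 87277746 reads. Loci called for 24 nt RNAs numbered 17372 and held 42.0% of reads, and 407 loci called for 21 nt RNAs held 19.2%. Another 6930 loci, marked N in place of a size, held 37.9%. Of all reads, 32.6% were 24 nt long and 19.6% were longer. The 74 loci marked as microRNA genes held 8.17% of reads, of which 92.8% were 21 nt long. The 10 largest loci held 45.3% of all reads.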

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

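The tests of exchanged denominators, of exchanged UTR values, of exchanged coding labels, of mixed-in RNA, of the count ratio between tables and of dsRNA against poly(A) RNA were chosen after the result was seen.

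Poly(A) counts of IPS1 and AT5G03545 had log2 changes of -6.45 and -5.19 in the noncoding table and rose in the coding table, every library of each condition going the other way; this difference was not tested. A fall of these RNAs that the coding table hides through exchanged poly(A) columns is argued against by its other genes: their replicate differences followed footprints of the same-named condition, with a correlation 0.362 higher than with the other condition, and from 0.306 to 0.406 higher over 18 settings. An error limited to the coding counts of these transcripts was not tested. AT5G03545 was the 1 transcript of 3 in both tables with at least 100 counts in every poly(A) library, and its ratio of noncoding to coding counts varied by 157% (CV) as labelled but by 0.977% with the conditions exchanged. The same ratio of IPS1, which had fewer counts, ran from 1.00 to 1.29 with the conditions exchanged and from 0.00122 to 1060 as labelled. An exchange of labels may therefore account for these transcripts. Whether the poly(A) columns are exchanged for every transcript cannot be told apart from a narrower error. The correlation of replicate differences with footprints, same minus other condition, was -0.107 against a bound of -0.1. Its count minimum had not been fixed, and over 18 settings it ran from -0.256 to -0.05 with 13 at the bound.

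SPX1 differed 6.18-fold in poly(A) RNA and 4.60-fold in footprints between control replicates 2 and 1, and not in dsRNA. Low phosphate RNA mixed into control replicate 2 is argued against. SPX1 would need 39.9% of it, a share with which no gene could rise 8-fold, yet 30 other genes rose at least 8-fold. Their needed share, with a median of 0.288% and a highest of 12.3%, was capped by that fold minimum. Their median could thus not have come near the value of SPX1. Over the 185 raised genes, chosen without a fold minimum, the median was 4.69%. SPX1 did not stand alone: PAP17, a phosphatase gene named after its values were seen and not called in poly(A) RNA, differed 2.83-fold in poly(A) RNA, had 50.8 and 112 CPM of footprints in control replicates 1 and 2, and would need 27.9%, and 10 of 185 raised genes would need over 20%. A difference that arose before library preparation may be involved, but the replicate difference over 185 raised genes correlated between poly(A) RNA and footprints at only 0.343, between the bounds of 0.1 and 0.5, which leaves it open. Some lists differed between these replicates alike in both assays, the sulfate list by -1.09 and -1.18 and photosynthesis genes by 1.37 and 0.99. No biological explanation was tested.

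The denominators of the UTR table's poly(A) libraries did not follow the coding totals. With control and low phosphate denominators exchanged, the ratio varied by 0.370% (CV) against 34.8% as named, so an exchange of denominators is a candidate explanation. An exchange of the UTR values themselves is argued against, since the lowest correlation with the same-named coding library was 0.600 and the highest with the exchanged library -0.216.

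In an edgeR interaction fit of both assays, 20482 genes were tested. The log2 change was higher in dsRNA than in poly(A) RNA for 354 genes and lower for 74, whichever sign the changes had. The dsRNA libraries came from another extract, line label and kit than the poly(A) libraries. This difference therefore cannot be told apart from one of extract, line or kit. TI1, a trypsin inhibitor gene named after its values were seen, had the difference 3.59 ± 0.32 (edgeR adjusted p = 4.28e-06).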

How the results depend on the processing

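The alternatives with exchanged labels or denominators, recovered reads, footprint and poly(A) libraries as pairs, all library sizes from the coding table, dsRNA without organelle genes and AT2G01021, a uORF pseudocount of 50 and a uORF mean score of at least 300 were chosen after the data were seen. RLE and DESeq2 were not run on uORFs, since their unit is a score. The 50-read minimum removed no small RNA locus and so tested nothing. Where 1 library was left out, the lone sample was assumed to vary like the other groups. The cause of the shifts below was not tested.

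Translational efficiency of genes gave 3 higher and 5 lower with footprint and poly(A) libraries as pairs and 0 in every other setting. With the control pairs, the low phosphate pairs or all pairs crossed it gave 0, with 397, 219 and 99 at an unadjusted p under 0.05 by edgeR. DESeq2 and limma voom gave 0 for those pairings too. With same-numbered pairs the root hair list was called higher (camera adjusted p = 0.0195) and the ribosomal protein and photosynthesis lists lower (7.13e-06 and 3.22e-08), each lost at 0.537 with an estimated correlation. The 235 poly(A) and 237 footprint calls were all kept under DESeq2, without the filter and with the replicate block. Separate fits per assay kept 180 and 159 of them, and RLE scaling 234 and 237. Of 2765 dsRNA calls, 1696 were kept under DESeq2, 2385 with the replicate block, 2578 without the filter, 2750 with RLE scaling and 2685 without organelle genes and AT2G01021. Poly(A) counts, higher then lower, became 315 and 111 with DESeq2, and 285 and 86 without the filter. Footprint counts became 320 and 157, and 300 and 125. Deviations of same-numbered control and low phosphate libraries correlated at -0.02 in footprints, -0.02 in dsRNA and 0.16 in poly(A). Between footprints and poly(A) of a condition they correlated at 0.37 in control and 0.54 in low phosphate, across genes of 2 libraries each. The labels do not state whether same-numbered libraries share material. With the replicate block, poly(A) gave 296 and 126, footprints 275 and 143, ncRNA efficiency 2 lower, uORF poly(A) 0 and 0, and 5' UTRs 0 and 0 in poly(A) and 0 higher in footprints. With the replicate block, 3' UTRs gave 40 and 13 in poly(A), 140 and 73 in footprints and 20 and 18 in efficiency. DESeq2 gave 486 dsRNA genes lower.

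For noncoding RNAs DESeq2 gave 9 and 4 in footprints and 1 lower in efficiency. Own-table library sizes gave 2 higher in poly(A), 35 higher in footprints and 36 and 2 in efficiency. Coding sizes for all columns gave 0 and 15 in poly(A) and 1 lower in efficiency. Exchanged labels gave 24 and 1 in poly(A) and 0 and 0 in efficiency. The share of noncoding RNAs above the coding percentile was 32.6% with a prior count of 2 and 23.3% with at least 50 poly(A) counts.

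For uORFs in poly(A), no filter gave 0 and 0, own-table scaling 8 higher, a pseudocount of 50 0 lower (and 1 higher in footprints), and a mean score of at least 300 0 and 0. In 5' UTRs a pseudocount of 0.1 gave 48 and 67 in poly(A), 1 higher in footprints and 2 higher in efficiency. Recovered reads gave 2 lower in poly(A) and 10 and 6 in footprints, and exchanged denominators 13 and 25 in poly(A). In 3' UTRs a pseudocount of 0.1 gave 6 and 1 in poly(A) and 22 and 4 in footprints, and no filter 7 lower in footprints. Recovered reads gave 54 and 10 in poly(A), 22 higher in footprints and 0 and 0 in efficiency. Exchanged denominators gave 0 and 0 in poly(A), 24 and 5 in footprints and 1 and 0 in efficiency. Gene lists called in efficiency fell from 2 to 0 with an estimated correlation and to 0 with fry, and in dsRNA 3 were called with an estimated correlation.

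Without 1 library at a time, counts ran from 52 to 199 higher and 7 to 49 lower in poly(A), from 74 to 164 and 16 to 48 in footprints, and from 624 to 2925 and 195 to 2293 in dsRNA. For noncoding RNAs they ran from 0 to 2 and 9 to 29 in poly(A), 8 to 14 and 0 to 55 in footprints, and 17 to 23 and 0 to 34 in efficiency. For uORFs they ran from 0 to 12 and 0 to 86 in poly(A), 0 to 1 higher in footprints, and 0 to 4 and 0 to 2 in efficiency. The uORF to coding ratio ran from 0 to 54 and 0 to 36. In 5' UTRs they ran from 0 to 68 and 0 to 56 in poly(A), 0 to 226 and 0 to 53 in footprints, and 0 to 13 and 0 to 5 in efficiency. In 3' UTRs they ran from 1 to 52 and 1 to 17 in poly(A), 16 to 933 and 3 to 551 in footprints, and 2 to 215 and 1 to 140 in efficiency. The highest UTR footprint counts came without control footprint replicate 2, and the highest 5' UTR poly(A) counts without low phosphate replicate 1. The noncoding share ran from 23.2% to 36.3%.

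Among the named coding genes, direction turned for 3 uncalled ones. Among all called genes, 2 changed sign in dsRNA without low phosphate replicate 1. For noncoding RNAs 1 call changed sign in footprints without control footprint replicate 2, and 1 in efficiency without control footprint replicate 1 or low phosphate poly(A) replicate 1. With exchanged labels 25 changed sign in poly(A) and 13 in efficiency. Without 1 library at a time, the log2 change of RPL18 ran from -0.22 to 0.053 in footprints, above 0 without control replicate 2. In dsRNA it ran from -0.12 without low phosphate replicate 1 to 0.14 and was -0.07 without control replicate 2. PHO1 ran from -0.14 to 0.079 in dsRNA, the latter without low phosphate replicate 2, and was 0.078 without control replicate 2. FLS1 ran from -0.89 without low phosphate replicate 2, where it was called, to 0.12 without low phosphate replicate 1.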

Other observations

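The tests of the plastid genes and of the chromosome 3 transcripts were chosen after the result was seen, as were the genes named here.

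AT2G45135, which follows SPX3 in the reference annotation, rose in dsRNA by 7.61 ± 0.42 (n = 2 per condition, edgeR adjusted p = 1.08e-71). Its poly(A) counts were 2 and 0 in control and 152 and 92 in low phosphate (edgeR adjusted p = 0.0188). AT2G34210, next to a microRNA gene of the phosphate response, rose by 7.20 ± 0.38 in dsRNA (edgeR adjusted p = 1.22e-74). Its poly(A) counts were 0 and 3 in control and 111 and 67 in low phosphate (edgeR adjusted p = 0.0168). The strand of these reads is not given in the sources used here, so reads of overlapping neighbours cannot be separated.

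Plastid-encoded genes had 4 of the lowest unadjusted p in the efficiency test, led by ATCG00140 at -2.15 ± 0.46. With footprint and poly(A) libraries as pairs, 3 of the 5 genes called lower by edgeR were plastid-encoded: ATCG00330, ATCG00140 and ATCG00470. Over 72 plastid genes the median change was -0.70 in footprints, with 72 of 72 below 0 (camera p = 0.00475 with an estimated correlation), and -0.04 in poly(A) RNA, with 37 below 0 (p = 0.471). The ratio was below 0 for 61. The photosynthesis list, nuclear genes that mark green tissue, had a ratio median of -0.41, with 21 of 23 below 0, and its footprints differed by 0.99 between control replicates 2 and 1, against 0.15 for the plastid genes. A lower footprint to poly(A) ratio of the set may be present, but the test leaves it open. Camera gave p = 0.0547 for the ratio with an estimated correlation, and 0.0849 with footprint and poly(A) libraries as pairs. Plastid genes held 0.599% to 1.07% of the footprint counts of a library and 0.0641% to 0.0916% of its poly(A) counts. The tagged protein is one of the cytosolic ribosome, and capture of plastid ribosomes through it was not tested. The ratio of plastid genes is therefore not read as translational efficiency.

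The 19 chromosome 3 transcripts with fewer footprints held 1520 and 995 footprints in control and 49 and 87 in low phosphate. In all poly(A) libraries together they held 87 reads. Whether their fragments came from translating ribosomes was not tested. Reads shared between copies of a repeat could give them similar counts; their control counts varied by 36.0% (CV) around a median of 137, between the 30% and 100% set as bounds, so this cannot be told apart from transcripts that change alone.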
